A study of Homo sapiens with 6 samples.

How the data were processed

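Total RNA from 6 subcutaneous tumours of human PC-3 cells was hybridised to 1-colour Affymetrix arrays. Per the labels' protocols, RNA was extracted with a column kit and biotinylated cRNA was made by the manufacturer's standard protocol. Per the submitters' processing notes the values were made with RMA, a method that in general corrects background, normalizes by quantiles and summarises probes into probe sets. The version of RMA and its settings are not given in the sources used here. The deposited values are linear intensities of probe sets, which was read from the values: none is negative, and arrays run from a minimum near 21 to a maximum between 26393 and 28477. RMA usually writes log2 values, and the step that made them linear is not given in the sources used here. No detection calls were used here, so whether a dim probe set was above background is unknown, and folds of dim genes may be compressed.

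Log2 was taken of every intensity, with values under 1 set to 1, which applied to 0 values. The design had foreseen log2 values as deposited and allowed for this step. The 68 Affymetrix control probe sets were left out, which left 22215. Gene names came from the platform annotation, with symbols updated through the gene identifier in the RefSeq table of assembly GRCh38.p14, which also gave chromosomes and the order of genes. Of the tested probe sets 19065 had 1 gene, 1043 several and 2107 none, and genes were named from the first kind only. Each of the 11963 genes was represented by its probe set with the highest mean over the 6 arrays. Among 51 named genes, 29 had several probe sets, 3 of these (UTS2, KLF6 and EZR) had probe sets of both signs, and 0 had both signs past the threshold.

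Samples were grouped by the line number in their titles, 3 of line 78 and 3 of line 82. Differences are line 82 minus line 78. They were tested with limma 3.58.1 in R 4.3.3, using lmFit and eBayes without trend, all 6 arrays and no covariates. P-values were adjusted by Benjamini-Hochberg over all 22215 probe sets, with calls at an adjusted p under 0.05. For EPB41L3 an exact permutation test of 3 against 3 arrays was added. Gene lists were tested with camera at a preset inter-gene correlation of 0.01 and adjusted over 22 lists. Camera with an estimated correlation and fry served as alternatives. By fry's directional test 3 lists passed (angiogenesis and growth factors, integrins, and metastasis suppressors), and by its test for change in either direction 17 did. Neither fry test compares a list with other genes. Chromosomes 1 to 22 and X were tested with camera in the same way. Whole chromosomes were used because no bands were at hand, and chromosome Y was left out although it met the minimum of 20 genes.

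The lists and the rule for named genes were fixed before the data were examined. The rule takes EPB41L3, the 10 largest increases and 10 largest decreases among called genes with non-overlapping groups, and up to 3 called members of each list with the largest differences. Where a list had no called member, the member with the largest difference is given. Y-linked genes and XIST were left out. Older symbols of list members were updated only where the symbol is no longer in use. The lists are general knowledge lists: the protein 4.1 and membrane skeleton, epithelial, mesenchymal, protease, integrin, metastasis suppressor, invasion, cell cycle, apoptosis, interferon, cytokine, hypoxia, angiogenesis, prostate, neuroendocrine, cholesterol, unfolded protein, immediate early, stroma, blood, muscle and ribosomal lists.

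The test was checked on simulated data for this comparison, in 5 runs of 22215 probe sets with 200 changed in each. Changes of 1.41-fold, 2-fold and 4-fold were recovered in 72.2%, 99.7% and 100% of cases, and 7.27% of calls were false. These rates hold for simulated probe sets drawn independently of each other. They cannot show how limma performs when an array departs from the others of its line in many genes, as was seen in the data. A list shifted by 0.3 log2 among 11963 genes was found in 5 of 5 runs, and 0 of 105 tests of lists without a shift passed. The simulated probe sets were drawn independently, so this check cannot show how camera behaves when the members of a list are correlated. In the data the estimated correlation was 0.64 in the interferon list and 0.54 in the cell cycle list, and as low as -0.023 in the integrin list.

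Alternatives planned beforehand were quantile normalization, median centring, 2 filters on dim probe sets, a trended and robust variance model, the replicate number as a block, the mean of a gene's probe sets, other list tests, adjusted p under 0.01, an unmoderated test, leaving out each array in turn, and counting replicate 2 of line 82 with line 78. Repeating the chromosome test under these settings, other than the estimated correlation, was added after seeing the data, as was the unmoderated test for EPB41L3. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.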

Results

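Gene expression was measured in 6 tumours, each on 1 Affymetrix array of 22283 probe sets. PC-3, a human prostate cancer cell line first grown from a bone metastasis, was the parent of both tumour lines compared. The series design sets a primary line against a line from a metastasis. The tumours grew under the skin of nude mice, a strain without functional T cells. Line 78 gave 3 tumours and is labelled poorly metastatic, and line 82 gave 3 tumours. Replicates 1 and 3 of line 82 are labelled highly metastatic. Replicate 2 of line 82 carries the words poorly metastatic in its genotype label and the number 82 in its genotype and title. It was analysed with line 82, by its number. The labels call the tumours biological replicates without saying whether each came from its own mouse, so p-values measure the spread between these samples. The number of arrays limits the precision of every value below.

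The line 78 tumours had median probe set intensities of 252, 251 and 255, and the line 82 tumours of 249, 247 and 251, in the order of the replicate numbers. Spearman correlations over probe sets were 0.991 to 0.997 between arrays of the same line and 0.987 to 0.992 between lines. The median SD of a probe set within a line was 0.084 log2 in line 78 and 0.11 log2 in line 82, over 3 arrays each. Without replicate 2 of line 82 it was 0.070 log2 in that line, over 2 arrays, which is not directly comparable with an SD over 3. Replicate 2 of line 82 stood apart from its sister arrays. In it 518 genes lay more than 0.5 log2 from the mean of the other 2 line 82 arrays, against 139 and 116 genes in replicates 1 and 3. On the first principal component, with 49.1% of the variance, the lines separated, and on the second, with 23.9%, this array lay at -24.70 while the other 5 lay between 2.04 and 8.50. Its ribosomal RNA control probe sets had a mean of 7.96 log2, and those of the other 5 arrays lay between 8.64 and 10.24. The GAPDH control, whose 5' signal minus its 3' signal is a sign of RNA quality, read -0.0096, -0.11 and -0.042 log2 in line 78 and -0.30, -0.16 and -0.14 in line 82, so every line 82 array lay lower. The same value for the actin control was 0.095, -0.049 and 0.14 log2 in line 78 and -0.21, -0.36 and 0.083 in line 82, where the lines overlapped.

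**Figure D1:**
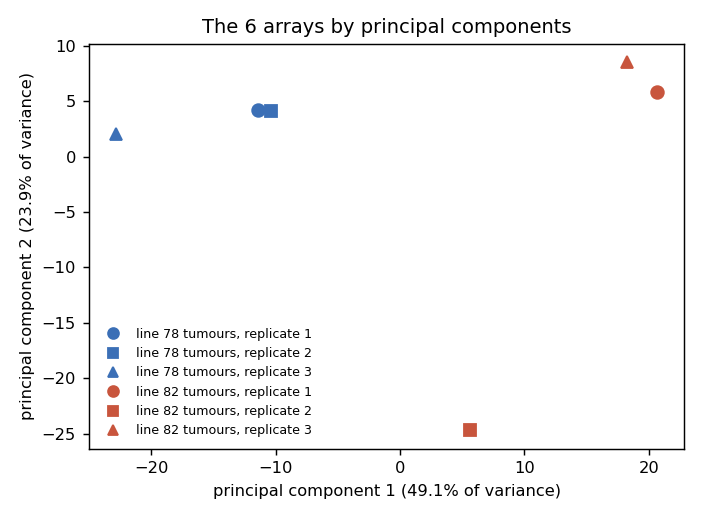
The 6 arrays by the first and second principal components of log2 intensity over all tested probe sets, with the share of variance on each axis. Colour marks the line and shape the replicate number, and replicate 2 of line 82 lies at -24.70 on the second axis, away from the other 5 arrays.

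The series title names protein 4.1B, so its gene EPB41L3 was compared first. EPB41L3, on chromosome 18, encodes an adaptor that ties membrane proteins to the spectrin and actin skeleton. Its RNA was lower in line 82 than in line 78 in every array and on each of its 3 probe sets. On the brightest, 206710_s_at, the level was 8.04 ± 0.15 log2 in line 78 (SD, n = 3) and 6.77 ± 0.10 log2 in line 82 (SD, n = 3). The log2 difference was -1.27 (SE 0.095), a 2.41-fold lower level, with a limma adjusted p of 0.0011.

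The other probe sets of EPB41L3 gave log2 differences of -1.38 (211776_s_at, limma adjusted p = 0.0040) and -1.27 (212681_at, limma adjusted p = 0.00273). An exact 2-sided permutation test gave p = 0.1 for each EPB41L3 probe set, which is the smallest p that 3 arrays against 3 can give. EPB41L3 was a dim signal in line 82: the brightest probe set lay at percentile 26.8 of all probe sets there and at percentile 51.2 in line 78, so the measured fold may understate the difference. With replicate 2 of line 82 counted with line 78, after the words of its genotype label, the EPB41L3 difference was -1.01 log2 and did not pass (limma adjusted p = 0.179), nor did the unchanged -1.27 log2 in a test without variance moderation (adjusted p = 0.103). In that array the 3 EPB41L3 probe sets read 6.84, 6.09 and 5.38 log2, each below the lowest line 78 tumour.

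**Figure D2:**
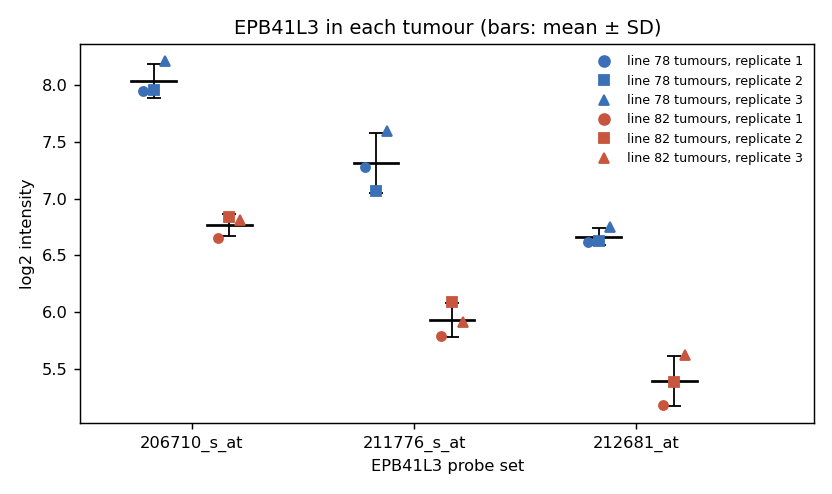
Log2 intensity of the 3 EPB41L3 probe sets in each of the 6 tumours, with the mean and SD of each line (n = 3). On 206710_s_at the line 82 tumours sit between 6.66 and 6.84 and the line 78 tumours between 7.95 and 8.21.

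Over all genes, the line 82 tumours had more RNA for TNFRSF11B, CEACAM5 and SLPI, among others, and less for UTS2, DNM3 and SPARC. TNFRSF11B encodes osteoprotegerin, a decoy receptor that binds the bone-resorption signal RANKL, and its level was 9.01 ± 0.17 log2 in line 82 against 6.90 ± 0.23 in line 78 (SD, n = 3 each), a 4.32-fold difference. CEACAM5, the carcinoembryonic antigen of epithelial cell surfaces, was 4.19-fold higher (11.29 ± 0.22 against 9.23 ± 0.29 log2). UTS2, the gene of the vasoactive peptide urotensin II, showed the largest measured difference of any named gene. It read 5.20 ± 0.28 log2 in line 82 and 9.05 ± 0.22 in line 78, a measured 14.4-fold lower level. In line 82 it lay at percentile 5.37 of all probe sets, so the measured fold may understate the difference. The same holds for DNM3, at percentile 29.2 in line 82, and for MAGEA6 and TNFRSF11B, at 18.9 and 29.0 in line 78. SPARC, a matrix glycoprotein, was 5.03-fold lower (8.20 ± 0.25 against 10.53 ± 0.020 log2).

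The 10 genes with the largest increases were MAGEA6, TNFRSF11B, CEACAM5, SLPI, CEACAM6, TGM2, IGFBP3, THBS1, RBPMS and PI3, with log2 differences from 2.12 to 1.44. SLPI and PI3 encode secreted inhibitors of neutrophil elastase, and their log2 differences were 1.82 and 1.44. TGM2, a protein-crosslinking transglutaminase, differed by 1.67 log2, and IGFBP3, which binds insulin-like growth factors, by 1.54. THBS1, a matrix glycoprotein that restrains vessel growth, differed by 1.53 log2, and the RNA-binding protein gene RBPMS by 1.51. CEACAM6, a surface relative of CEACAM5, differed by 1.68 log2. The MAGEA6 value of 2.12 log2 comes from a probe set that can cross-hybridise with other members of the MAGE-A family, so it is uncertain which member it reports.

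The 10 genes with the largest decreases were UTS2, DNM3, SPARC, MDK, GJA1, MDFIC, HSD17B2, NAP1L3, DSC2 and TENM4, with log2 differences from -3.85 to -1.31. DNM3, a dynamin that pinches off membrane vesicles, was 6.98-fold lower (log2 difference -2.80). MDK, the heparin-binding growth factor midkine, differed by -1.55 log2, and the gap junction gene GJA1 by -1.53. HSD17B2, which oxidises oestradiol and testosterone to weaker steroids, differed by -1.49 log2, and the desmosomal cadherin DSC2 by -1.44. MDFIC differed by -1.53 log2, NAP1L3 by -1.44 and TENM4 by -1.31. UTS2 was called on 220784_s_at alone, since its other probe set, 220785_at, was dim in both lines and differed by 0.0063 log2 (limma adjusted p = 0.984). CEACAM5 was likewise called on 201884_at alone, and its other probe set, 217291_at, differed by 0.029 log2 (8.07 against 8.04, limma adjusted p = 0.928). Replicates did not overlap between the lines for any of these 20 genes, as the naming rule required, and their limma adjusted p lay between 0.000116 (UTS2) and 0.0157 (GJA1). With any 1 array left out they stayed past the threshold in all 6 fits, except TGM2 (5 of 6), TENM4 (4 of 6) and GJA1 (2 of 6).

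**Figure D3:**
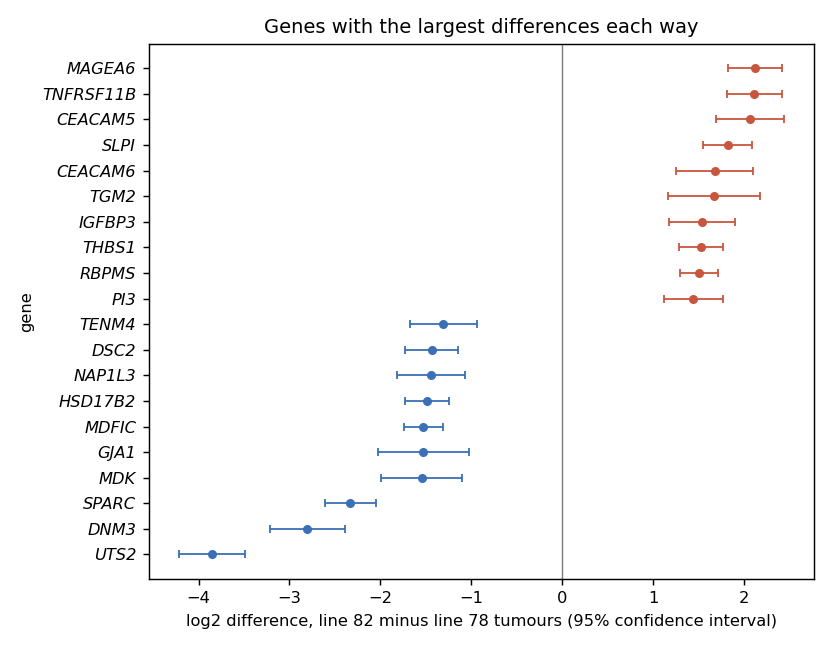
Log2 difference between line 82 and line 78 tumours for the 10 genes with the largest increase and the 10 with the largest decrease, with 95% confidence intervals from limma (n = 3 per line). The values run from -3.85 for UTS2 to 2.12 for MAGEA6. No interval includes 0, which follows from the naming rule, since it took only genes called in the same fit.

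In the limma test, 474 of 22215 probe sets passed an adjusted p of 0.05, 189 higher and 285 lower in line 82, and 72 of them differed at least 2-fold, 36 each way. By gene, 279 of 11963 passed, 133 higher and 146 lower. With quantile normalization 139 genes were higher and 150 lower, and with median centring 137 were higher and 122 lower. Which direction holds more genes thus depends on the scaling. By probe set, more were lower under each scaling. Quantile normalization gave 205 higher and 293 lower, and median centring 196 higher and 236 lower. The groups did not overlap for 4214 probe sets, or 19.0%, against the 10% that chance gives for 3 arrays against 3. Other groupings of the same 6 arrays into 3 and 3 reached up to 3525 probe sets, or 15.9%. Without replicates 1, 2 or 3 of line 78 the count of probe sets was 204, 180 or 136, and without replicates 1, 2 or 3 of line 82 it was 184, 1520 or 168. With replicate 2 of line 82 counted with line 78, limma called 0 probe sets. At an unadjusted p under 0.05 it then had 4306 probe sets, more than the 3313 of the original groups. A test without variance moderation on the original groups also called 0 (2517 unadjusted). Of the 46 named genes called, 23 passed in all 6 fits that leave out 1 array, and 15 passed in under 3: BIK, ELF3, EZR, FBN1, GJA1, GSN, HOXB13, HSP90B1, IGFBP6, KLF6, MCAM, PTGS2, RIGI, SPRY4 and TNFAIP6. Of the 25 called named genes with several probe sets, 13 were called on their brightest alone: CCN1, CEACAM5, CXCL8, DSC2, ELF3, EZR, GSN, HSP90B1, ITGB4, KLF6, KRT7, MDFIC and UTS2.

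Among 22 gene lists fixed before the data were examined, 8 passed in limma's camera test with a preset correlation, 6 higher and 2 lower in line 82, and 0 passed with an estimated correlation (lowest adjusted p = 0.347). The 5' minus 3' signal of the GAPDH control, lower in every line 82 array, moves with the same lines as each list and chromosome below. The interferon response list had the lowest adjusted p, 7.81e-10, but an adjusted p = 0.612 with an estimated correlation. Of its 39 measured genes, 36 had positive differences, with a median of 0.36 log2, while 1 gene, the viral RNA sensor RIGI, was called (0.58 log2, adjusted p = 0.0341). Its members with the largest differences, IFI27 at 1.23 log2 and OAS1 at 1.01, did not pass singly (adjusted p = 0.228 and 0.125). Without replicates 1, 2 or 3 of line 78 the called interferon genes numbered 0, 4 or 0, and without replicates 1, 2 or 3 of line 82 they numbered 0, 7 or 0. Per array, the interferon list's median stood at -0.056, 0.28 and -0.18 log2 in line 78 and at 0.55, 0.20 and 0.46 in line 82, so replicate 2 of line 78 lay above replicate 2 of line 82.

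The cytokine and chemokine list was higher, with 5 of 28 measured genes called higher and 0 lower (adjusted p = 1.45e-07, or adjusted p = 0.455 with an estimated correlation). These were CXCL8 (1.17 log2), CXCL3 (7.81 ± 0.12 against 6.81 ± 0.40 log2, SD, n = 3 each) and CXCL2 (0.78), which attract neutrophils, with TNFAIP6 (0.92) and the NF-kB inhibitor NFKBIA (0.77). CXCL2 and NFKBIA lie outside the naming rule and were added after their values were seen. Adjusted over the list alone, 10 members passed. Its called members numbered 2, 0 and 2 without replicates 1, 2 and 3 of line 78, and 3, 9 and 0 without those of line 82. Of 39 genes for angiogenesis and growth factors, 6 were higher, among them IGFBP3, THBS1 and IGFBP6 (1.05 log2), and 0 lower. This list had an adjusted p of 2.86e-06, or 0.347 with an estimated correlation, and adjusted over the list alone 8 members were higher and 1 lower. Among the 6, THBS1 is known to restrain vessel growth, and IGFBP3 and IGFBP6 bind and sequester growth factors. The rest of the 6 are not described here, so these roles do not stand for the list. Its members called higher numbered 5, 3 and 4 without replicates 1, 2 and 3 of line 78, and 3, 9 and 3 without those of line 82, with 2 lower in the fit without replicate 2 of line 82.

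Of 23 metastasis suppressor genes, 2 were higher in line 82, the actin-severing protein gene GSN (0.63 log2) and the transcription factor gene KLF6 (0.50), and 0 lower. The list was higher, with a median of 0.14 log2 and an adjusted p of 0.00351, or 0.347 with an estimated correlation. GSN and KLF6 were each called on 1 probe set: 214040_s_at of GSN differed by 0.10 log2 (adjusted p = 0.836), and 208960_s_at and 211610_at of KLF6 by 0.20 (0.473) and -0.033 (0.946). Adjusted over the list alone, 7 members were higher and 0 lower. Its called members numbered 2, 0 and 0 without replicates 1, 2 and 3 of line 78, and 0, 4 and 0 without those of line 82, and the median was 0.091 log2 without replicate 3 of line 78. Of 26 immediate early genes, CCN1 (0.82 log2) and KLF6 were called higher and the signalling inhibitor gene SPRY4 lower (-0.75). The immediate early list was higher, with an adjusted p of 0.00625, or 0.519 with an estimated correlation, and adjusted over the list alone 6 members were higher and 2 lower. Its members called higher numbered 2, 1 and 0 without replicates 1, 2 and 3 of line 78, and 1, 6 and 0 without those of line 82. Among 17 neuroendocrine markers 1 gene was called, the secretory granule chaperone gene SCG5 (1.32 log2), and also 1 adjusted over the list alone. The neuroendocrine list had an adjusted p of 0.0255, or 0.617 with an estimated correlation. Its call was lost without replicate 3 of line 78 (adjusted p = 0.249) and without replicate 3 of line 82 (adjusted p = 0.0965).

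The cell cycle list was lower in line 82, with 39 of 40 measured genes below 0 and a median of -0.18 log2 (adjusted p = 2.79e-06, or adjusted p = 0.612 with an estimated correlation). None of its genes passed, by all genes tested or adjusted over the list alone (0 each), and TOP2A had the largest difference, -0.59 log2 (adjusted p = 0.251). Without replicate 3 of line 78 the cell cycle median was -0.087 log2, and without replicate 1 of line 82 it was -0.097. Without replicate 2 of line 82 it was -0.27, and 3 genes were called lower. Its per-array medians were -0.083, -0.13 and 0.19 log2 in line 78 and -0.36, -0.061 and -0.20 in line 82, so replicate 2 of line 82 lay above 2 of the line 78 tumours. Of 20 cholesterol and lipid synthesis genes 0 were called, also adjusted over the list alone, and FASN, the fatty acid synthase, differed by -0.61 log2 (adjusted p = 0.323), while 2 were called lower without replicate 2 of line 82. The cholesterol list was lower, with a median of -0.15 log2 and an adjusted p of 0.0068, or 0.505 with an estimated correlation. Without replicate 2 of line 82, the array that stood apart, 0 of the 8 list calls were lost.

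**Figure D4:**
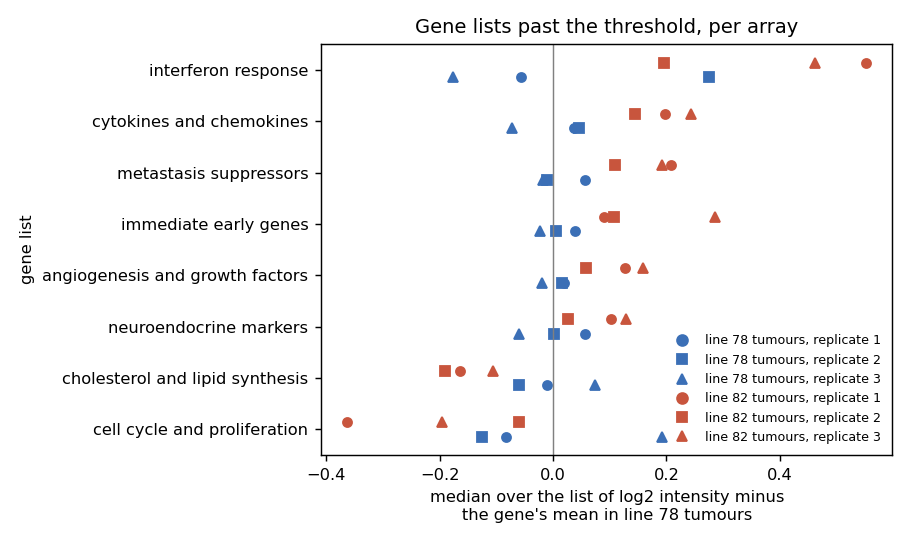
Median over each gene list of log2 intensity minus the gene's mean in line 78 tumours, for the 8 lists past the threshold in the camera test, 1 point per array. In the interferon list line 82 sits between 0.20 and 0.55 and line 78 between -0.18 and 0.28.

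The other 14 lists did not pass, though several held called genes, 27 calls in all. These numbered 18, 14 and 15 without replicates 1, 2 and 3 of line 78, and 17, 56 and 14 without those of line 82. In the list of protein 4.1 and the membrane skeleton, EPB41L3 was lower and EZR, the membrane-to-actin linker ezrin, was higher (0.57 log2), with 26 of 28 genes not past the threshold and the same 1 gene each way adjusted over the list alone. EZR had 5 probe sets, with values from -0.00013 to 0.57 log2. Among 32 epithelial junction and keratin genes, 3 were higher, including KRT7 (1.27 log2) and the epithelial transcription factor gene ELF3 (1.03), and 3 were lower, including DSC2 (5 and 3 adjusted over the list alone). Of 29 mesenchymal genes, 3 were higher, including TGFBI (0.64 log2), and 2 lower, SPARC and the microfibril gene FBN1 (-0.54), with 6 and 4 adjusted over the list alone. Of 34 extracellular protease and inhibitor genes, 2 were higher, including SLPI, and 2 lower, the collagenase gene MMP1 (-0.94 log2) and the stromelysin gene MMP10 (-0.76), with 7 and 3 adjusted over the list alone. Among 26 integrins and matrix receptors, the hemidesmosome integrin ITGB4 was higher (13.57 ± 0.13 against 12.57 ± 0.10 log2, SD, n = 3 each) and 0 were lower, with 5 and 0 adjusted over the list alone.

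Of 26 invasion and bone metastasis genes, TNFRSF11B and the prostaglandin synthase gene PTGS2 (0.97 log2) were higher and MMP1 lower, with 5 and 2 adjusted over the list alone. Among 16 prostate and androgen response genes, the prostate homeobox gene HOXB13 was lower (-0.96 log2, 11.57 ± 0.25 against 12.54 ± 0.23, SD, n = 3 each) and 0 were higher, the same adjusted over the list alone. Of 29 apoptosis regulators, BIK, a pro-apoptotic BCL2 relative, was higher (0.77 log2) and 0 lower, the same adjusted over the list alone. Of 22 unfolded protein response genes, the chaperone gene HSP90B1 was lower (-0.42 log2) and 0 higher, with 2 higher and 1 lower adjusted over the list alone. Of 35 hypoxia and glycolysis genes 0 were called, LOX stood at -0.72 log2 (adjusted p = 0.0568) on its brightest probe set and at -0.79 on 204298_s_at (adjusted p = 0.0256), and 1 was higher and 4 lower adjusted over the list alone. Of the settings tried, the hypoxia list passed, as lower, only without replicate 3 of line 78 (adjusted p = 0.049). Of 25 ribosomal protein genes 0 were called, also adjusted over the list alone, and RPS19 differed by 0.25 log2 (adjusted p = 0.252). The median and mean had different signs in the mesenchymal list (0.055 and -0.041 log2), the hypoxia list (0.021 and -0.0013) and the stroma list (0.0084 and -0.016), and camera gave higher, lower and lower.

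Markers of other cell types that a tumour in a mouse could hold were examined as lists too. Of 25 stroma and vessel markers, the fibrillar collagen gene COL3A1 (-0.91 log2) and the endothelial adhesion gene MCAM (-0.48) were lower and 0 higher, with 2 each way adjusted over the list alone. Among 25 muscle, fat and skin markers, the fat cell gene FABP4 was lower (-1.13 log2) and 0 higher, with 1 each way adjusted over the list alone. The list as a whole had an adjusted p of 0.0583 and passed, as higher, without replicate 1 of line 78 (0.0188) or replicate 1 of line 82 (0.0211). Of 23 blood and immune cell markers 0 were called, also adjusted over the list alone, and S100A9 differed by 0.35 log2 (adjusted p = 0.225). Mouse RNA of the host that binds these human probes was not separated from tumour RNA, so each value can hold both.

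By chromosome, genes on chromosomes 15, 3 and 10 were lower as groups in line 82 and genes on chromosome 19 higher, by small amounts. With an estimated correlation 15 and 3 held (adjusted p = 0.0362 each), and 10 and 19 did not (adjusted p = 0.166 and 0.683). The median of the 360 genes on chromosome 15 was -0.050 log2 (3 genes called higher, 7 lower), that of the 655 on chromosome 3 was -0.044 (4 higher, 8 lower), and that of the 451 on chromosome 10 was -0.026 (3 higher, 15 lower). The 810 genes on chromosome 19 had a median of 0.038 log2, with 6 called higher and 1 lower. Adjusted p in limma's camera test over 23 chromosomes was 0.00243, 0.00481, 0.0214 and 0.0325 for chromosomes 15, 3, 10 and 19. Another grouping of the same arrays, with replicates 1 and 2 of line 78 and replicate 2 of line 82 on 1 side, called 11 chromosomes.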

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

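The tests on the array that stood apart were chosen after it was seen to stand apart, and among them the implied share of line 78 RNA had its bounds set before its value was seen. Of 68 Affymetrix control probe sets, which were left out of the tests over all probe sets, 3 were higher in every line 82 array than in every line 78 array, where chance alone gives 5%. AFFX-PheX-M_at was higher by 0.0857 log2 (4.86 against 4.78). AFFX-r2-Bs-dap-M_at was higher by 0.148 log2 (4.87 against 4.72). AFFX-r2-P1-cre-3_at, a bright control, was higher by 0.177 log2 (13.75 against 13.57). Their number does not exceed the share that chance alone gives, and no explanation was tested for these 3. Another probe set for cre, AFFX-r2-P1-cre-5_at, overlapped between the lines (13.36 to 13.64 log2 in line 78 and 13.42 to 13.62 in line 82).

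Replicate 2 of line 82 differed from its sister arrays by more than 0.5 log2 in 518 genes, 197 of them lower and 321 higher. A tumour of line 78 under the wrong number is argued against: on a scale from the line 78 mean (0) to the mean of the other line 82 arrays (1), its median position was 0.828 over 63 genes called at 2-fold or more without it (quartiles 0.609 and 1.03). Line 78 RNA mixed in is argued against as the only source, since 75.9% of the departing genes (393) lay outside the range of the other 5 arrays, and 50% by more than 0.2 log2. A small share stays open: this test replaced an earlier one that decided nothing, in which the implied median share was 12.9%, between the bounds of 10% and 20%, and over the 5 genes of at least 4-fold it was -1.37% (highest 15.8%). The position and the share rest on genes picked for a large difference in the other 5 arrays, which can pull both towards line 78. Neither was computed for the other line 82 arrays, so they lack a baseline. A difference in RNA or target preparation may contribute. Replicate 2 of line 82 was the lowest of 6 arrays in 9 of 9 control probe sets named for 18S or 28S ribosomal RNA or HUMRGE. Several of these report parts of the same RNA, so they are not 9 separate signs. It was also the lowest in the actin control's 5' minus 3' signal (-0.36 log2), though not in that of GAPDH (-0.16). A biological difference of this tumour was not tested and stays open.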

How the results depend on the processing

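Unless stated, the alternatives were planned before the data were examined, and no called result reversed. The EPB41L3 difference stayed past the threshold in 12 alternatives, between -1.31 and -1.18 log2 with adjusted p of at most 0.0108, and the filter for the brighter probe sets left no value because its brightest probe set is below their median. In the unmoderated test, added for this gene after seeing the data, the same -1.27 log2 did not pass (adjusted p = 0.103). With replicate 2 of line 82 counted with line 78 it was -1.01 log2 (limma adjusted p = 0.179). Limma then called 0 probe sets (4306 at an unadjusted p under 0.05, against 3313 in the original groups), 0 at 2-fold and 0 genes. In a test added after seeing the data, 7 chromosomes were then called. Adjusted p under 0.01 left 109 probe sets, and the unmoderated test 0 (2517 unadjusted). Camera with an estimated correlation passed 0 lists and 2 chromosomes, and fry passed 3 lists. For the moved array, the block below and the estimated correlation the cause was not tested.

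With the replicate number as a block, 298 probe sets and 173 genes were called, and 7 of 45 named genes called other than EPB41L3 were lost, while the muscle, fat and skin list was added (adjusted p = 0.0492). Over the tested probe sets, the deviations of same-numbered arrays correlated at 0.16, -0.14 and -0.12, with no common sign. Most of the control probe sets named for bioB, bioC, bioD or cre, all left out of the tests, fell with the replicate number in both lines. AFFX-BioB-M_at read 9.13, 8.84 and 8.68 log2 in line 78 and 9.26, 9.15 and 8.91 in line 82. A few, such as AFFX-CreX-3_at, did not keep that order (13.37, 13.41 and 13.12 in line 82). In every one of these controls replicate 3 lay below replicate 1 in both lines. For these controls the replicate number thus points to a shared step. Whether such a step moved the tested probe sets stays open, since their deviations had no common sign.

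Leaving out 1 array gave 136 to 1520 probe sets, 56 to 108 at 2-fold, 90 to 857 genes, 7 to 9 lists and 2 to 5 chromosomes. All 279 genes were among the 857 called without replicate 2 of line 82. Without replicates 1, 2 and 3 of line 78, 129, 108 and 90 genes were called, and without replicates 1 and 3 of line 82, 118 and 102. Of the 45 named genes, 36, 29 and 27 kept their call without replicates 1, 2 and 3 of line 78, and 32, 45 and 24 without those of line 82. Fewer arrays lower the power, while the count rose without replicate 2 of line 82. The median SD of line 82 was then 0.070 log2 over 2 arrays, not directly comparable with 0.11 log2 over 3. The cause of the rise was not tested.

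Quantile normalization and median centring lost 0 list calls. The filter for brighter probe sets lost the neuroendocrine list (adjusted p = 0.967) and the cholesterol list (0.0748), and the milder filter the neuroendocrine list (0.153). The moved array lost the metastasis suppressor list (0.078) and the cholesterol list (0.127). The mean of a gene's probe sets added the integrin list and the muscle, fat and skin list (0.0356 each). Of 352 list tests, 14 that passed on neither side changed direction in camera, 7 of them with 1 array left out. Signal over background is unknown, since no detection calls were used.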

Other observations

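The gene families here were chosen after their values were seen, so their counts are descriptions, and each count is given with its values under the scaling alternatives where these differ. Genes of retinoid metabolism and binding, receptors included, were lower in line 82 in 4 of 12 measured cases and higher in 0. Of the 12, 7 had positive differences (8 with median centring). ALDH1A3, which makes retinoic acid, was lower (10.86 ± 0.082 log2 in line 82 against 11.86 ± 0.13 in line 78, SD, n = 3 each, limma adjusted p = 0.00242). CYP26A1, which degrades retinoic acid, differed by -0.97 log2 (adjusted p = 0.0103), the retinol carrier gene RBP4 by -0.93 (0.0215) and the retinoic acid binding protein gene CRABP2 by -0.47 (0.0135). DHRS3 stood at 0.64 log2 (adjusted p = 0.0602) and CYP26B1 at 0.31 (adjusted p = 0.103), without overlap between the lines. Of 6 desmosomal cadherins, DSC2 and DSC3 (-0.96 log2, adjusted p = 0.0184) were lower and 0 higher, while DSG2 stood at 0.42 log2 (adjusted p = 0.13).

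Of 14 trefoil factor and mucin genes, the mucosal peptides TFF2 (2.27-fold, 1.18 log2, adjusted p = 0.00922) and TFF1 (0.79 log2, adjusted p = 0.042) were higher and 0 lower. With quantile normalization 1 of them, TFF2, was called. TFF3 stood at -0.78 log2 (adjusted p = 0.135). In the CEACAM family 2 of 8 genes, CEACAM5 and CEACAM6, were higher and 0 lower. All 8 metallothionein genes had positive differences, under both scalings too, but 1 was called, MT1M (0.92 log2, adjusted p = 0.00324), and probes of this family cross-hybridise. Of 24 HOX genes, HOXB6 (0.88 log2, adjusted p = 0.0028) and HOXC6 (0.49, adjusted p = 0.0106) were higher and HOXB13 lower. Positive differences were seen in 22 of the 24 (23 with median centring), most of them not called.

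The tests in the next 3 paragraphs were chosen after their patterns were seen, and for the run of genes the bounds of the copy number test and of the test without replicate 2 were set before their values were seen. EPB41L3 was lower in line 82. A faulty probe set is argued against, since the probe set that changed least still differed by -1.27 log2. Loss of the wider region is argued against as well: the 5 nearest measured genes on each side, from MTCL1 (-0.40 log2, adjusted p = 0.291) to LAMA1 (0.19), had a median of 0.0137 log2, and 0 of the 10 were called. A loss confined to EPB41L3, or a change in its regulation, was not tested and stays open.

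A run of 75 neighbouring genes on chromosome 10, from JMJD1C to GHITM, was shifted down in line 82, with a median of -0.20 log2, 76% of genes below 0, 8 called lower (among them DNAJC12 at -0.89 log2 and PPIF at -0.50) and 0 called higher. Scanning windows of 25 genes found 15 runs, some of them overlapping, on 8 chromosomes, 12 shifted down and 3 up. This run held the most extreme window median (-0.304 log2). By the median of the whole run, HHIPL2 to ITPKB on chromosome 1 (-0.221) and the overlapping ZWINT to TSPAN15 on chromosome 10 (-0.208) lay further from 0. Chance order is argued against, as 0 of 1000 random orders gave a window as far from 0, and so is replicate 2 of line 82 as its only source, since the median without that array was -0.233 log2. A difference in DNA copy number stays open: the 55 brighter genes had a median of -0.251 log2, with 45 below 0, and the 20 dim genes one of -0.0308, which met the bound set for it, but dim signals are compressed under any cause, so this gives it little support. Other splits of the arrays shifted this run by at most 0.083 log2, but their most extreme windows anywhere, relative to each split's median gene, reached 0.264 against 0.312 for the lines (-0.304 before that centring), so the scan also picks up structure among the arrays.

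The 6 arrays split into 3 and 3 in 10 ways, too few for a share under 0.05. Every split other than the real one mixes the lines on both sides. A difference between the lines then adds to the spread within each side and lowers the number of calls. The counts of the other splits are therefore not the level that chance alone would give. The real split alone (1 of 10) gave as many probe sets (474, highest other 0), 2-fold probe sets (72, highest other 0), genes (279, highest other 0) and lists (8, highest other 5). For chromosomes 2 of 10 splits gave as many, the real one with 4 and another with 11. That other split set replicates 1 and 2 of line 78 with replicate 2 of line 82, which points to a structure of the arrays apart from the lines. It follows the mean of the ribosomal RNA control probe sets. This mean was 8.64, 9.12 and 7.96 log2 in those arrays. It was 10.06 in replicate 3 of line 78, and 10.24 and 9.27 in replicates 1 and 3 of line 82. Whether what sets that signal also shifted the chromosomes was not tested.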
